A study of Homo sapiens with 4 samples.

How the data were processed

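The data were 4 libraries of poly(A)-selected RNA from Daoy cells, sequenced as 100-nucleotide single reads per the labels' protocols. Groups were taken from the sample titles: 3 libraries labelled wild type, numbered 1 to 3 there, and 1 labelled ARID1B shRNA. The series design names vector-only and parental cells as controls, and the labels do not say which wild-type library is which; the controls were therefore treated as 1 group. The labels give no batch or date, and the deposited file of the library labelled ARID1B shRNA carries a number outside the run of those of the wild-type libraries.

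The deposited values were counts of reads per gene, 1 file per library, with no normalization. Per the submitters' processing notes, bcl2fastq, HISAT2, HTSeq and DESeq2 were used with the GRCh37 (hg19) build; the versions, the HTSeq mode, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes are uncertain. The last 5 lines of each file name no gene and were left out of library sizes and tests. Of the reads of that kind, those outside genes made up 7.38% ± 0.293 (SD, n = 3) of reads counted as genic, ambiguous or outside genes in wild type and 5.27% in the library labelled ARID1B shRNA, and ambiguous reads made up 6.59% ± 0.157 and 7.12% of genic reads. The files hold 57820 versioned Ensembl gene identifiers. Of these 52338 (90.5%) matched, without the version number, an entry of the GENCODE annotation of GRCh38 used here for symbols, gene types, GC content and length of the longest transcript. Because that build differs from the authors' build, no coordinates are given. A RefSeq gene table of GRCh38.p14 served only to tell which genes neighbour each other.

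Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, at its minimum count of 10 and minimum total of 15, which left 17024 genes. Libraries were scaled by TMM, and the library labelled ARID1B shRNA was compared with the wild-type libraries by glmQLFit with robust shrinkage and glmQLFTest. That fit has 2 residual degrees of freedom, all from the wild-type libraries, and assumes that the lone library varies as they do. P-values were adjusted by Benjamini-Hochberg over all tested genes, and 0.05 was the threshold throughout. The standard error of a log2 fold change was its absolute value divided by the square root of F. Each wild-type library was compared with the other two in the same way. Intervals of the CPM of the library labelled ARID1B shRNA are exact 95% Poisson intervals, those of shares of reads are exact 95% Clopper-Pearson intervals, and a gene at 0 counts is bounded by a floor of 3 counts; these cover counting error only. No pair of libraries was a duplicate: the chi-square of gene counts per degree of freedom was 25.8 or more in each of the 6 pairs. The wild-type pairs correlated at 0.966 to 0.980 in log-CPM, across genes, and the pairs with the library labelled ARID1B shRNA at 0.920 to 0.945.

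Of 35 gene lists fixed before the data were examined, 33 had at least 5 tested genes. The list of 13 mitochondrially encoded mRNAs had 0 counts in every library and the list of blood and immune markers had too few tested genes, so neither was tested. Of the 729 list genes 4 matched no identifier. Lists were tested with camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 33 lists. Genes were named by a rule that was also fixed before the data were examined: ARID1B; the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among those that passed, had a mean log2 CPM of at least 3 and lay outside the wild-type range; up to 4 members of each list with the smallest p; and any SWI/SNF subunit. A gene that this rule names is not reported here. Mitochondrial-type gene copies and the genes near CDKN2B were chosen after their values were seen.

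A smooth trend of each library on GC content and gene length was estimated by loess (span 0.3) over genes with a mean count of at least 20 and removed through offsets. GC content was known for 97.6% of the tested genes. Other alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, the 2 quasi-likelihood methods of edgeR, no robust shrinkage, no filter, a mean count of at least 50, glmTreat against 1.5-fold, leaving out each wild-type library, camera with an estimated correlation or on ranks, fry, and 10000 random lists matched on expression. Chosen after seeing the data were the later quasi-likelihood method, genes of 40% to 55% GC content only, random lists matched on GC content as well, and the trend removal for ARID1B and for the wild-type comparisons.

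The procedure was tested on simulated counts with 3 libraries against 1, at the means and depths of these libraries. All simulated libraries shared the same dispersion trend, without gene-specific spread or batch, and the recovery run had no GC trend. Recovery and false calls below hold for that simpler setting and not for the measured libraries. Of genes changed 2-fold, 31.3% of 67 were recovered, of genes changed 4-fold 82.1% of 67, and of genes changed 8-fold 95.5% of 66, with 11 unchanged genes called among 16371 tested. A GC trend planted in 13121 simulated genes, with a Spearman correlation of 0.593, went to -0.00491 after its removal. Changes of about 2-fold were thus often not detectable at this depth and number of libraries, even in that simpler setting.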

Results

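Gene expression was measured by RNA sequencing in Daoy, an established human medulloblastoma cell line, to ask which genes and signalling pathways differ when ARID1B is lowered. ARID1B is a DNA-binding subunit of the BAF form of the SWI/SNF chromatin remodelling complexes. A short hairpin RNA (shRNA), which lowers its target mRNA through RNA interference, was encoded in a lentiviral vector that doxycycline switches on. Per the labels, the cells received doxycycline at 1 µg/ml for 72 h before RNA extraction. The data comprised 4 libraries, of which 3 were labelled wild type and 1 was labelled ARID1B shRNA. The wild-type libraries held 12619786, 13228587 and 15390106 reads assigned to genes, and the library labelled ARID1B shRNA held 8792848. Levels are given as library-scaled CPM (read counts scaled to a common library total) with the mean ± SD of the 3 wild-type libraries. A single library stood for the shRNA arm, so its values have no replicate, and the spread in every test came from the wild-type libraries. Nothing in the labels said that the wild-type libraries came from separate cultures, so p-values measured only the spread between these libraries. That spread went beyond counting error, with a chi-square of gene counts per degree of freedom of 25.8 or more in each pair. It may mix technical differences with differences between kinds of control cells. The series design names vector-only and parental cells, and the labels do not say which library is which. The deposited file of the library labelled ARID1B shRNA carries a number outside the run of the wild-type files; if it was prepared or sequenced in a separate batch, that batch and the group cannot be told apart.

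The target gene came first as a check of the labels. ARID1B (ENSG00000049618.17) was not lower in the library labelled ARID1B shRNA. It stood there at 175 CPM, from 1533 counts, against 164, 88.0 and 72.9 CPM in wild-type libraries 1, 2 and 3. The log2 fold change was 0.69 with a standard error (SE) of 0.46, above each wild-type library but not beyond their replicate error (edgeR adjusted p = 0.399). Without wild-type library 1, ARID1B was higher in the library labelled ARID1B shRNA by 1.12 on the log2 scale (edgeR adjusted p = 0.026). With each library's trend on GC content and gene length removed, the change was -0.20 with an SE of 0.61 (edgeR adjusted p = 0.873). The measured mRNA level thus did not show the lowering that the label names, although the value with the trend removed leaves one open. Every direction below is one of the library labelled ARID1B shRNA against the wild-type libraries.

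Few of the other SWI/SNF subunit genes passed the test. Of 27 tested subunits 1, BCL7B, rose, from 79.9 ± 8.30 to 163 CPM (log2 fold change 1.03, edgeR adjusted p = 0.0402), and 2, BCL7B and BICRA, rose with p adjusted over the list alone. BICRA, a subunit of the non-canonical BAF complex, measured 7.23 ± 1.95 and 23.3 CPM (log2 fold change 1.68, edgeR adjusted p = 0.0531 over all genes), and -0.49 with the GC and length trend removed (0.288). The BCL7B call ended with the trend removed (0.43, edgeR adjusted p = 0.155) and without wild-type library 2 (edgeR adjusted p = 0.0772) or 3 (0.058). ARID1A, the paralogue that takes the place of ARID1B in BAF complexes, measured 147 ± 19.7 CPM in wild type and 204 CPM in the library labelled ARID1B shRNA (edgeR adjusted p = 0.203). The ATPase genes SMARCA4 and SMARCA2 had log2 fold changes of 0.66 and -0.51 (edgeR adjusted p = 0.148 and 0.147), and SMARCB1 and ARID2 had 0.15 and -0.08 (0.654 and 0.799). The subunits as a list did not shift by camera, as measured or with the GC and length trend removed. Their median log2 fold change was 0.10 as measured and turned to -0.18 with the trend removed.

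**Figure D1:**
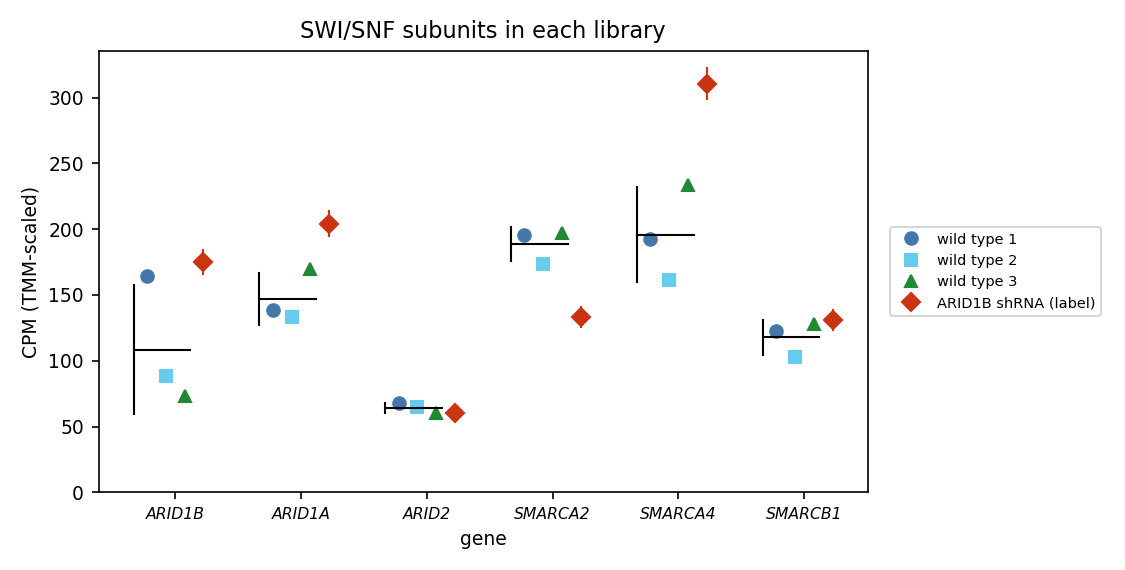
CPM of ARID1B and 5 other SWI/SNF subunit genes in each library, on a linear axis from 0. Symbols are single libraries, black lines the mean and SD of the 3 wild-type libraries, and red bars the exact 95% Poisson interval of the library labelled ARID1B shRNA; ARID1B lies at 175 CPM there, above the 164, 88.0 and 72.9 CPM of the wild-type libraries.

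Across the transcriptome, genes of the amino acid and integrated stress response stood among the largest increases in the library labelled ARID1B shRNA. GDF15, a stress-induced cytokine of the TGF-beta family, rose 189-fold, from 1.46 ± 0.798 to 280 CPM. TRIB3 and CHAC1, both targets of the transcription factors ATF4 and CHOP, rose 26.5-fold and 26.1-fold, and DDIT4 and SESN2, which restrain mTORC1, rose 32.9-fold and 19.8-fold. INHBE, ADM2, CCDC85B and CDC42EP1 rose by 4.25, 4.43, 6.05 and 4.54 on the log2 scale. FTH1, the ferritin heavy chain, rose from 42.5 ± 27.4 to 920 CPM, a value that is uncertain because the gene has many near-identical pseudogene copies. The edgeR adjusted p of these 10 genes lay between 0.0149 for GDF15 and 0.0342 for FTH1. With the GC and length trend removed, the log2 fold change went from 7.56 to 6.50 for GDF15, from 6.05 to 4.35 for CCDC85B, from 4.73 to 3.88 for TRIB3 and from 4.71 to 3.73 for CHAC1. It went from 4.54 to 2.98 for CDC42EP1, from 4.43 to 3.25 for ADM2 and from 4.31 to 3.60 for SESN2, and these 7 genes passed. DDIT4 went from 5.04 (SE 0.68) to 4.56 (SE 0.72) and FTH1 from 4.43 (SE 0.62) to 4.49 (SE 0.73), so that with similar changes and larger errors they no longer passed (edgeR adjusted p = 0.0712 and 0.0792). Both were also lost with no filter on low counts (0.21 and 0.244), and FTH1 among genes of 40% to 55% GC content (0.0735). GDF15, CCDC85B and TRIB3 passed without each wild-type library in turn. For every gene of which this is said, here and below, the edgeR adjusted p without library 2 lay just below 0.05. The split from genes just above that threshold is thus a narrow one. Without wild-type libraries 2 and 3, DDIT4 had an edgeR adjusted p of 0.0865 and 0.0894 and INHBE of 0.0576 and 0.052. CHAC1, CDC42EP1, FTH1, ADM2 and SESN2 had 0.0665, 0.0565, 0.0979, 0.0574 and 0.051 without library 2, and FTH1 had a log2 fold change of 5.08 without library 3.

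Among the largest decreases, NCALD, a neuronal calcium sensor, fell from 25.2 ± 7.61 to 1.25 CPM, and CHRNA9, a nicotinic acetylcholine receptor subunit, from 117 ± 10.4 to 15.6 CPM. TGFB3, a TGF-beta ligand, and FAP, a surface protease of activated fibroblasts, fell 8.47-fold and 7.67-fold. ADAMTS16 fell 7.37-fold, METTL7A 7.34-fold, ARHGAP28 6.90-fold and CUBN 6.77-fold, and TNFRSF19, a receptor of the TNF family, fell 9.45-fold. CDKN2B, which encodes the CDK4 inhibitor p15, had 0 counts against 12.5 ± 7.02 CPM in wild type. A floor of 3 counts, 0.342 CPM in the library labelled ARID1B shRNA, puts CDKN2B at least 36.6-fold lower. Its neighbours MTAP, KLHL9 and IFNA4 were at 0 counts there as well. The value of CDKN2B therefore need not reflect regulation of that gene, as described under other observations. The edgeR adjusted p of these 10 genes lay between 0.0149 for CHRNA9 and 0.0432 for CDKN2B. With the trend removed TNFRSF19 went from -3.24 (SE 0.54) to -3.08 (SE 0.60) on the log2 scale and CDKN2B stayed at 0 counts (SE 1.77 and 1.83), so that with similar changes and larger errors they no longer passed (edgeR adjusted p = 0.0712 and 0.0639). CHRNA9, TGFB3, FAP, ADAMTS16 and CUBN passed without each wild-type library in turn. Without library 2 the edgeR adjusted p was 0.0629 for NCALD, 0.0524 for METTL7A and 0.05 for ARHGAP28, and without library 3 it was 0.0802 for METTL7A, 0.0753 for TNFRSF19 and 0.0703 for CDKN2B. With limma-voom 4 of the 10 were lost, CDKN2B (0.107), NCALD (0.0506), TNFRSF19 (0.066) and METTL7A (0.0561), and among genes of 40% to 55% GC content CDKN2B (0.0737) and TNFRSF19 (0.0577).

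In all, 763 of 17024 tested genes differed at an edgeR adjusted p below 0.05, 621 higher and 142 lower, and 747 of them by at least 2-fold. With the GC and length trend removed 550 genes differed, 342 higher and 208 lower, so the share of higher genes went from 81.4% to 62.2%; 407 genes were called both ways, all with the same sign. The count was 1189 without wild-type library 1, 157 without library 2 and 478 without library 3. Of the 73 genes named here that passed, 50 also passed with the trend removed, 25 passed without each wild-type library in turn, and 20 passed under both.

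GC content separated the libraries. In the library labelled ARID1B shRNA, the median log2 ratio to wild type went from -0.28 in the decile of genes with the lowest GC content to 1.35 in the decile with the highest. Wild-type library 3 ran the same way against the other wild-type libraries (-0.17 and 0.56), library 2 ran the opposite way (0.18 and -0.51), and library 1 was flat (-0.01 and -0.05). Across genes, which are not independent replicates, log2 fold change and GC content had a Spearman correlation of 0.472. Of the 621 higher genes 405 lay in the top 2 deciles of GC content, as did 1 of the 142 lower genes.

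**Figure D2:**
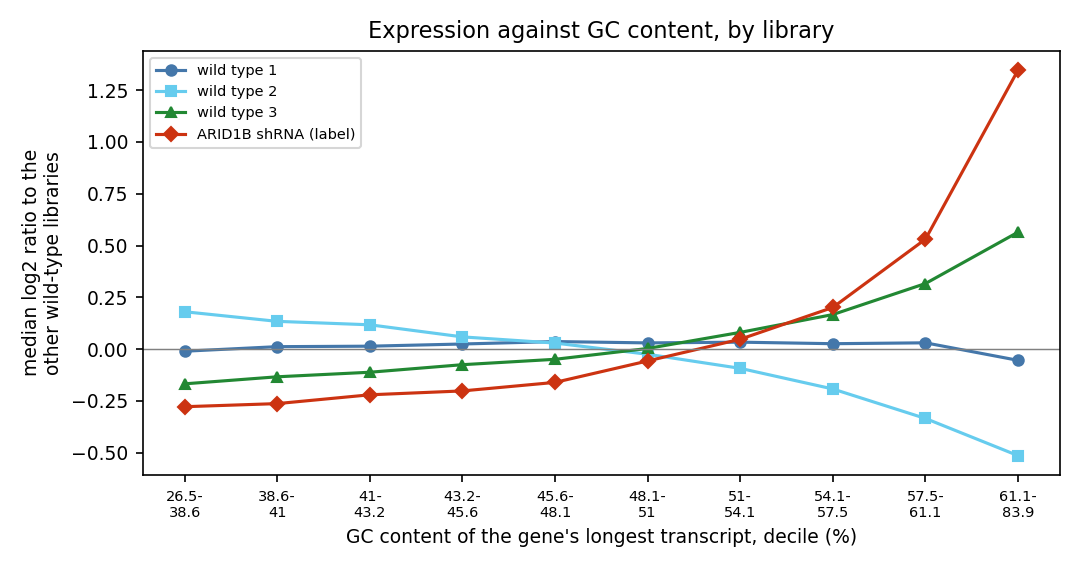
Median log2 ratio of each library to the other wild-type libraries (y axis) in deciles of the tested genes ordered by GC content (x axis, range of each decile in percent). The line of the library labelled ARID1B shRNA ends at 1.35, that of wild-type library 3 at 0.56 and that of wild-type library 2 at -0.51.

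Among 33 gene lists, 14 shifted against the other genes by camera with its preset correlation, 8 up and 6 down. None of the 14 held with an estimated correlation, where 0 lists passed at an adjusted p or an unadjusted p below 0.05; that correlation rests on 2 residual degrees of freedom. With the trend removed 10 of the 14 held. None of the remaining lists passed camera with the trend removed.

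**Figure D3:**
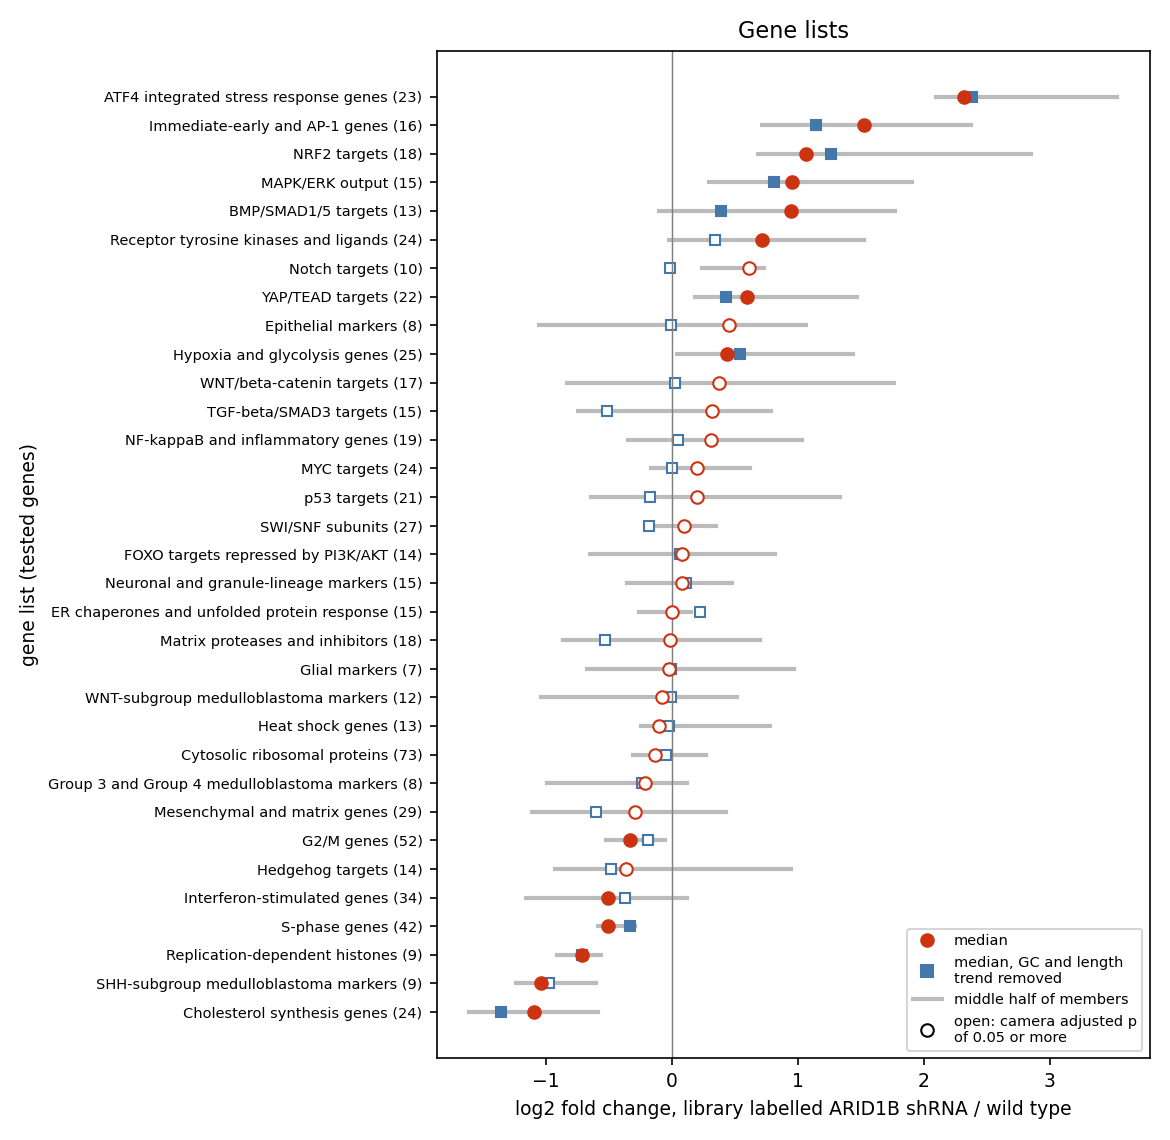
Median log2 fold change of each of the 33 tested gene lists (x axis; list and number of tested genes on the y axis), with red circles for the values as measured, blue squares for those with the GC and length trend removed, and grey bars from the lower to the upper quartile of the members. Filled symbols mark a camera adjusted p below 0.05; the ATF4 list stands highest at 2.32 and the cholesterol list lowest at -1.10.

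The integrated stress response rose as a whole. ATF4 directs this response to amino acid shortage and other stresses, and all 23 tested members of its list rose, both over all genes and with p adjusted over the list alone. ASNS, which makes asparagine, rose from 66.3 ± 2.73 to 330 CPM, PHGDH, the first enzyme of serine synthesis, from 161 ± 16.0 to 733 CPM, and SLC3A2, the heavy chain of amino acid transporters, from 95.9 ± 6.60 to 482 CPM. The edgeR adjusted p was 0.0149 for each of TRIB3, ASNS, SLC3A2 and PHGDH, and these 4 genes passed with the trend removed and without each wild-type library in turn. The list's median log2 fold change was 2.32 (camera adjusted p = 1.39e-16; adjusted p = 0.629 with an estimated correlation) and 2.38 with the trend removed, where 20 of the 23 members passed.

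The list of oxidative stress genes under NRF2 shifted up as well. Of 18 tested NRF2 targets 8 rose and 10 did not pass, and 11 rose with p adjusted over the list alone. Thioredoxin reductase TXNRD1 rose from 292 ± 37.2 to 1567 CPM, the haem-degrading enzyme HMOX1 from 15.7 ± 3.76 to 125 CPM and the quinone reductase NQO1 from 57.9 ± 7.28 to 162 CPM (edgeR adjusted p = 0.0149, 0.0183 and 0.0251). TXNRD1 and HMOX1 passed without each wild-type library in turn, and NQO1 reached an edgeR adjusted p of 0.0565 and 0.0502 without libraries 2 and 3. The list's median log2 fold change was 1.06 (camera adjusted p = 3.99e-07; adjusted p = 0.629 with an estimated correlation). This list shares 1 gene with the ATF4 list.

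The list of cholesterol synthesis genes shifted down. Of 24 tested members 8 fell and none rose, and with p adjusted over the list alone 14 fell and 1 rose. Methylsterol monooxygenase MSMO1 fell from 66.2 ± 15.5 to 12.7 CPM, HMGCS1, which makes the substrate of the rate-limiting HMG-CoA reductase, from 104 ± 22.1 to 22.6 CPM, the isomerase gene IDI1 by 3.57-fold and squalene synthase FDFT1 from 134 ± 7.75 to 50.6 CPM. Their edgeR adjusted p lay between 0.027 and 0.0314, and below 0.05 with the trend removed as well. Without wild-type library 3 it was 0.0754 for MSMO1, 0.0729 for HMGCS1, 0.068 for IDI1 and 0.0502 for FDFT1, and without library 2 it was 0.05, 0.0576, 0.0565 and 0.0563. The list's median log2 fold change was -1.10 (camera adjusted p = 4.78e-06; adjusted p = 0.639 with an estimated correlation).

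**Figure D4:**
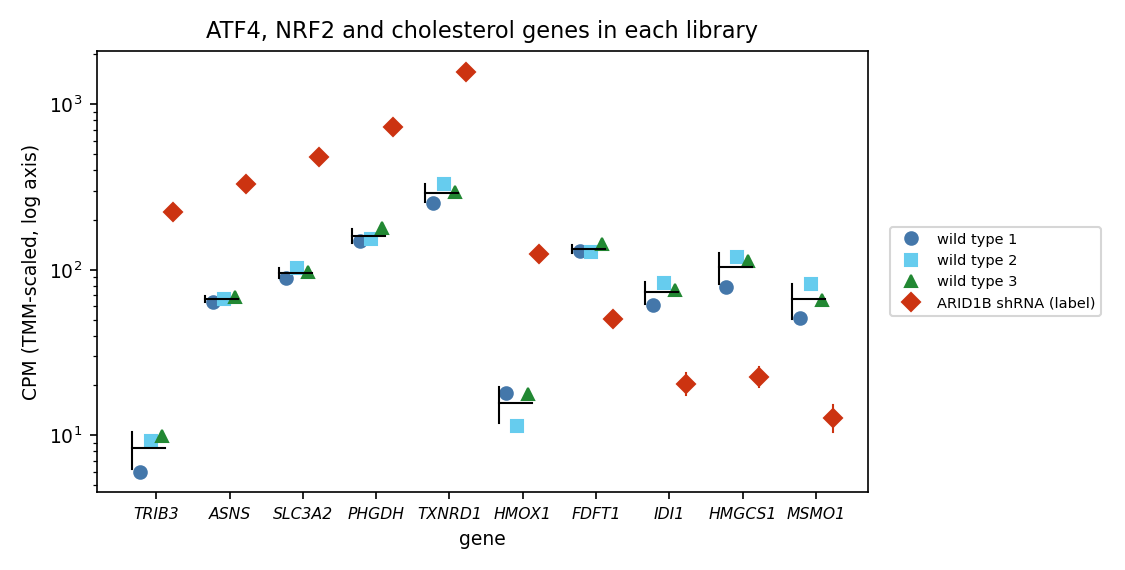
CPM on a log axis of 4 ATF4 targets (TRIB3, ASNS, SLC3A2, PHGDH), 2 NRF2 targets (TXNRD1, HMOX1) and 4 cholesterol synthesis genes (FDFT1, IDI1, HMGCS1, MSMO1) in each library. Black lines are the mean and SD of the 3 wild-type libraries and red bars the exact 95% Poisson interval of the library labelled ARID1B shRNA, which stands at 330 CPM for ASNS against 66.3 ± 2.73 and at 12.7 CPM for MSMO1 against 66.2 ± 15.5.

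The lists of immediate-early genes, MAPK/ERK output and receptor tyrosine kinases shifted up, with part of their genes passing. The immediate-early list shares ATF3 with the ATF4 list. With the GC and length trend removed fewer of its genes passed, and its median log2 fold change went from 1.53 to 1.14. Of 16 immediate-early and AP-1 genes 8 rose, or 11 with p adjusted over the list alone, among them ATF3 (52.5 ± 9.97 to 263 CPM), JUN (62.1 ± 12.7 to 301 CPM), FOSL1 (41.5 ± 10.1 to 356 CPM) and JUND (38.2 ± 3.33 to 120 CPM), with an edgeR adjusted p of 0.0183 to 0.0199. JUND turned to -0.54 with the trend removed (edgeR adjusted p = 0.465), FOSL1 went from 3.10 to 2.39 and passed, and JUN reached an edgeR adjusted p of 0.0538 without wild-type library 2. The list's median log2 fold change was 1.53 (camera adjusted p = 1.09e-05; adjusted p = 0.629 with an estimated correlation). Of 15 genes of MAPK/ERK output 3 rose, FOSL1, the receptor EPHA2 (7.73-fold) and the feedback inhibitor SPRY2 (3.76-fold), and 7 rose with p adjusted over the list alone. Its median was 0.95 (camera adjusted p = 0.0033; adjusted p = 0.761 with an estimated correlation), while its medians in wild-type libraries 1, 2 and 3, each against the other two, were -0.66, 0.52 and 0.23, and 3 members were lower in library 1. Of 24 receptor tyrosine kinases and ligands 2 rose, EPHA2 and the EGFR ligand EREG (7.39-fold), and 6 rose and 1 fell with p adjusted over the list alone. That list's median was 0.72 (camera adjusted p = 0.0274; adjusted p = 0.629 with an estimated correlation), and its call ended with the trend removed (0.177), without wild-type library 3 (0.0721), with genes of a mean count of at least 50 (0.126) and among genes of 40% to 55% GC content (0.134). Without single wild-type libraries the edgeR adjusted p rose to 0.0886 for EPHA2 without library 2, and to 0.129 for SPRY2 and 0.121 for EREG without library 3; with the trend removed EPHA2 went from 2.95 to 2.17 and passed, and SPRY2 from 1.91 to 1.99 and did not (0.0544).

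The lists of YAP targets, BMP targets and hypoxia genes shifted up, with 4, 3 and 4 single genes passing. Of 22 YAP/TEAD targets 4 rose, or 6 with p adjusted over the list alone; GADD45A rose 4.66-fold, AMOTL2 4.29-fold, FOXF2 3.17-fold and the matricellular gene CCN1 2.94-fold. Their median was 0.59 (camera adjusted p = 5.97e-04; adjusted p = 0.629 with an estimated correlation). Of 13 BMP targets 3 rose, DLX2 (5.93-fold), ID1 (3.42-fold) and MSX1 (5.09-fold), or 5 with p adjusted over the list alone. Their median was 0.95 (camera adjusted p = 0.0111; adjusted p = 0.629 with an estimated correlation), the call ended without wild-type library 3 (0.0815), and the direction turned among genes of 40% to 55% GC content (0.916). Of 25 hypoxia and glycolysis genes 4 rose, and with p adjusted over the list alone 11 rose and 1 fell. The lipase inhibitor ANGPTL4 rose from 0.398 ± 0.223 to 26.9 CPM, VEGFA from 167 ± 40.8 to 842 CPM, the stress-responsive gene NDRG1 by 4.34-fold and PFKFB3 from 31.9 ± 4.33 to 86.3 CPM. The hypoxia median was 0.44 (camera adjusted p = 0.00225; adjusted p = 0.629 with an estimated correlation). With the trend removed the medians were 0.43 for the YAP/TEAD list, 0.39 for the BMP list and 0.54 for the hypoxia list, against 0.59, 0.95 and 0.44. The BMP list also varied between wild-type libraries 1, 2 and 3, with medians of 0.24, -0.26 and -0.27, each against the other wild-type libraries. GADD45A, ANGPTL4, DLX2 and ID1 passed with the trend removed, ANGPTL4 with 4.93 against 6.01 and DLX2 with 1.84 against 2.57 on the log2 scale, and without each wild-type library in turn. With the trend removed AMOTL2 went from 2.10 to 1.59, FOXF2 from 1.66 to 0.44, MSX1 from 2.35 to 1.63, VEGFA from 2.33 to 1.35 and PFKFB3 from 1.44 to 1.04, and these 5 were lost (edgeR adjusted p = 0.0739, 0.434, 0.0918, 0.116 and 0.0671). Without library 2 the edgeR adjusted p was 0.0574 for FOXF2, 0.0567 for CCN1, 0.0565 for VEGFA, 0.0704 for NDRG1 and 0.0574 for PFKFB3, and without library 3 it was 0.061 for FOXF2, 0.0587 for MSX1, 0.059 for VEGFA, 0.06 for NDRG1 and 0.0669 for PFKFB3.

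The S-phase, G2/M and histone lists shifted down, although hardly any single gene passed. The histone list covers only transcripts kept by poly(A) selection, with 9 of its 16 members tested, and is not read here as a measure of S phase. None of 42 S-phase genes and none of 52 G2/M genes passed, over all genes or with p adjusted over the list alone, although 39 and 40 of them had negative log2 fold changes. At an unadjusted p below 0.05 the S-phase list had 20 genes, all lower, and the G2/M list 13 lower and 2 higher; DESeq2 called 3 and 4, and limma-voom 0 in both. The smallest p of the S-phase list was that of the replication helicase gene MCM6, 193 ± 12.6 and 104 CPM (edgeR adjusted p = 0.0527). That of the G2/M list belonged to a higher gene, RANGAP1, 143 ± 33.6 and 302 CPM (0.0786); the mitotic gene HMMR measured 91.2 ± 12.2 and 50.8 CPM (0.0913). The S-phase median was -0.51 (camera adjusted p = 3.58e-06; adjusted p = 0.685 with an estimated correlation). The G2/M median was -0.33 (camera adjusted p = 0.00827; adjusted p = 0.933 with an estimated correlation), and that call ended with the trend removed (0.295), among genes of 40% to 55% GC content (0.234) and without wild-type library 1 (0.0754); its medians in the wild-type libraries, each against the other two, were 0.26, -0.09 and -0.18. Of 9 replication-dependent histone genes 1 fell, H2BC21 (13.2 ± 1.24 to 3.31 CPM, edgeR adjusted p = 0.036), and the same number with p adjusted over the list alone. H2BC21 lost the call without library 2 (0.0677) or 3 (0.068), and histone gene copies share sequence, so their single values are uncertain. The histone median was -0.72 (camera adjusted p = 8.46e-04; adjusted p = 0.629 with an estimated correlation).

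The lists of interferon-stimulated genes and of markers of the SHH subgroup of medulloblastoma also shifted down. Of 34 interferon-stimulated genes 4 fell, and with p adjusted over the list alone 9 fell and 1 rose. OAS1, a sensor enzyme for double-stranded RNA, fell from 46.8 ± 9.78 to 11.5 CPM, PARP9 from 152 ± 39.1 to 33.8 CPM, and the transcription factor STAT2 from 161 ± 3.04 to 74.5 CPM. Their median was -0.51 (camera adjusted p = 0.0302; adjusted p = 0.956 with an estimated correlation), and the call ended with the trend removed (0.215) and without wild-type library 2 (0.0802) or 3 (0.205). The medians of the wild-type libraries, each against the other two, were -0.76, 0.16 and 0.63. OAS1, PARP9 and STAT2 had an edgeR adjusted p of 0.0351, 0.036 and 0.0323, against 0.0686, 0.05 and 0.0639 without library 2 and 0.0549, 0.0775 and 0.065 without library 3. PARP9 went from -2.17 to -2.01 with the trend removed and was lost (edgeR adjusted p = 0.0554). None of the 9 SHH-subgroup markers passed, over all genes or over the list alone (4 at an unadjusted p below 0.05; DESeq2 called 1 and limma-voom 0); EYA1 measured 9.96 ± 2.15 and 3.31 CPM (edgeR adjusted p = 0.0841). The SHH marker median was -1.04 (camera adjusted p = 0.0191; adjusted p = 0.685 with an estimated correlation), and the call ended with the trend removed (0.0876) and among genes of 40% to 55% GC content (0.327).

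Targets of WNT signalling, the pathway that defines the WNT subgroup, went both ways. DKK1, a secreted WNT inhibitor, rose from 1.82 ± 0.312 to 20.6 CPM and MYC from 15.6 ± 2.04 to 55.8 CPM, while TNFRSF19 fell and BMP4 fell from 13.1 ± 1.32 to 3.88 CPM (edgeR adjusted p = 0.0175, 0.0233, 0.0388 and 0.0435). AXIN2, a direct target that feeds back on the pathway, measured 5.40 ± 0.393 and 1.71 CPM (edgeR adjusted p = 0.0746). Of 17 tested WNT targets 2 rose and 2 fell, or 4 and 4 with p adjusted over the list alone, and the list did not shift (median 0.37, camera adjusted p = 0.711). DKK1 passed without each wild-type library in turn, whereas MYC, TNFRSF19 and BMP4 reached an edgeR adjusted p of 0.0523, 0.0753 and 0.0832 without library 3, and MYC and BMP4 of 0.05 and 0.0736 without library 2. Of 12 WNT-subgroup markers 2 rose, again DKK1 and MYC, and with p adjusted over the list alone 2 rose and 3 fell (median -0.08, mean 0.07, camera adjusted p = 0.995 with its direction down); the 2 lists share 7 genes.

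Other signalling lists did not shift by camera with its preset correlation. Some passed in alternatives: Notch up with DESeq2 (adjusted p = 0.0275), limma-voom (0.0445), no filter (0.0417) and without wild-type library 2 (0.0254), p53 up with DESeq2 (0.0027), MYC up against random lists (0.0483) and Hedgehog down against random lists matched on GC content (0.0427). Of 14 Hedgehog targets 1 rose, FOXF1 (8.11-fold; median -0.37, although camera's direction was up, camera adjusted p = 0.995). Of 10 Notch targets 2 rose, NOTCH1 (9.59-fold) and HES4 (23.6-fold; median 0.61, camera adjusted p = 0.072), and both were lost with the trend removed, where NOTCH1 went from 3.26 to 1.77 and HES4 from 4.56 to 2.09 on the log2 scale (edgeR adjusted p = 0.0592 and 0.0584) and the list's median was -0.02. HES4 had 5.25 without wild-type library 3. Of 15 TGF-beta targets 1 fell, the matrix protein gene TGFBI (7051 ± 506 to 2688 CPM, edgeR adjusted p = 0.0222), and with p adjusted over the list alone 3 rose and 2 fell (median 0.32, camera adjusted p = 0.85). Of 14 FOXO targets 2 rose, GADD45A and IRS2 (median 0.08, camera adjusted p = 0.548). Of 24 MYC targets 1 rose, RRP12, and 0 with p adjusted over the list alone (median 0.20, camera adjusted p = 0.196). Of 21 p53 targets 4 rose, GDF15, SESN2, CDKN1A (5.20-fold) and BBC3 (8.82-fold), and with p adjusted over the list alone 7 rose and 1 fell (median 0.20, camera adjusted p = 0.711). SESN2 belongs to the ATF4 list as well. With the trend removed the medians of the TGF-beta and p53 lists turned to -0.52 and -0.18. Those of the Hedgehog and FOXO lists kept their sign, while that of the MYC list went from 0.20 to 0.0021. With p adjusted over the list alone, the calls of the Hedgehog, Notch and FOXO lists were 1, 2 and 2 higher genes. Without wild-type library 2 the edgeR adjusted p was 0.0991 for NOTCH1, 0.0609 for TGFBI and 0.0964 for RRP12, and 0.05 for FOXF1 and BBC3, the latter with 0.0502 without library 3. With the trend removed IRS2 went from 2.25 to 1.31, RRP12 from 1.16 to 0.49, CDKN1A from 2.38 to 1.85 and BBC3 from 3.14 to 1.07, and all 4 were lost (edgeR adjusted p = 0.0516, 0.152, 0.128 and 0.122).

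No list of markers of other cell types shifted by camera with its preset correlation. The mesenchymal list passed, down, with DESeq2 (adjusted p = 0.0225), among genes of 40% to 55% GC content (0.0206) and against random lists matched on GC content (0.0132). Of 29 mesenchymal and matrix genes TWIST2 rose and VIM (2513 ± 125 to 937 CPM) and COL5A2 (298 ± 66.4 to 94.8 CPM) fell, and with p adjusted over the list alone 1 rose and 7 fell (median -0.30, camera adjusted p = 0.548). Of 18 matrix proteases and inhibitors 1 fell, TIMP2 (2.13-fold), over all genes and over the list alone (median -0.02, also with MMP13, at 0 counts, set to its bound; camera adjusted p = 0.843). Of 15 neuronal and granule-lineage markers 1 rose, ZIC2, and 2 rose and 1 fell over the list alone (median 0.07, mean -0.09, camera adjusted p = 0.85 with its direction up). None of 7 glial markers passed over all genes, and 1 rose with p adjusted over the list alone (1 at an unadjusted p below 0.05; DESeq2 called 1 and limma-voom 0); OLIG2 measured 0.427 ± 0.303 and 4.90 CPM (edgeR adjusted p = 0.0591; list median -0.02 with camera's direction up, camera adjusted p = 0.79). Of 8 epithelial markers KRT7 rose, over all genes and over the list alone (median 0.45, camera adjusted p = 0.716), and of 8 markers of Group 3 and Group 4 medulloblastoma RBM24 did (median -0.22, camera adjusted p = 0.843). Without wild-type library 2 the edgeR adjusted p was 0.0567 for VIM, 0.0784 for TWIST2, 0.0767 for TIMP2, 0.0629 for ZIC2, 0.0865 for KRT7, 0.086 for RBM24 and 0.05 for COL5A2, and without library 3 it was 0.0715 for TIMP2, 0.0923 for ZIC2, 0.0592 for KRT7, 0.111 for RBM24 and 0.0988 for COL5A2. With the trend removed TWIST2 went from 2.94 to 2.58, ZIC2 from 1.43 to 0.80 and KRT7 from 2.84 to 1.83, and all 3 were lost (edgeR adjusted p = 0.0519, 0.21 and 0.0839).

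Nor did the protein quality control, ribosomal and inflammatory lists by this test. Of 15 genes of ER chaperones and the unfolded protein response 1 rose, HERPUD1 (37.3 ± 6.32 to 88.5 CPM), and with p adjusted over the list alone 3 rose and 2 fell (median -0.00041, mean 0.17, camera adjusted p = 0.931 with its direction up). Of 13 heat shock genes 1 rose, HSPA1B, which has a near-identical paralogue and is uncertain for that reason, and 2 rose over the list alone (median -0.11, camera adjusted p = 0.913 with its direction up). None of 73 cytosolic ribosomal protein genes passed, over all genes or over the list alone (14 at an unadjusted p below 0.05; DESeq2 called 5 and limma-voom 0; median -0.14, mean 0.07, camera adjusted p = 0.716 with its direction down). None of 19 NF-kappaB and inflammatory genes passed, over all genes or over the list alone (1 at an unadjusted p below 0.05; DESeq2 called 1 and limma-voom 0; median 0.31, camera adjusted p = 0.31). The list passed, up, against random lists (adjusted p = 0.044), those matched on GC content (0.0268) and by camera without wild-type library 2 (0.0232). Of the 33 lists this one had the widest spread of medians between the wild-type libraries, 4.53 on the log2 scale. RELB, for example, measured 22.4 ± 12.1 and 77.5 CPM (log2 fold change 1.79, edgeR adjusted p = 0.173). Its edgeR adjusted p was 0.0156 without wild-type library 1, and with the trend removed its log2 fold change was 0.27 (0.876). The edgeR adjusted p was 0.111 for HERPUD1 and 0.0523 for HSPA1B without library 3, 0.0574 for both without library 2, and 0.0732 for HSPA1B with the trend removed, where it went from 1.47 to 0.89 on the log2 scale.

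Of the wild-type libraries, compared each with the other two, only library 1 had genes that passed. These comparisons have 1 residual degree of freedom each and were run by edgeR alone. Library 1 had 394 genes at an edgeR adjusted p below 0.05, 91 higher and 303 lower, and libraries 2 and 3 had 0 (897 and 512 at an unadjusted p below 0.05), although library 1 is in their reference pair and can widen their error. Both pairs that hold library 1 correlated less, at 0.966 with library 2 and 0.976 with library 3, than libraries 2 and 3 did (0.980). With the GC and length trend removed these correlations were 0.967, 0.977 and 0.985. ARID1B was among the higher genes of wild-type library 1 (log2 difference 1.01, edgeR adjusted p = 0.0168). Of its lower genes 9 were among the 19 NF-kappaB and inflammatory genes, 11 among the 34 interferon-stimulated genes and 8 among the 18 matrix proteases and inhibitors. The median of the NF-kappaB list, relative to the other two wild-type libraries, was -2.61 in library 1, 1.92 in library 2 and 0.77 in library 3 on the log2 scale. Of the 394 genes 3 were also among the 763 of the library labelled ARID1B shRNA, against 17.7 for independent lists, although a gene that varies between wild-type libraries is harder to call in the other comparison. With the GC and length trend removed the 394 became 0, with 1869 genes at an unadjusted p below 0.05.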

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

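One value outside the gene counts stood above the wild-type libraries. In the library labelled ARID1B shRNA, 7.12% (exact 95% interval 7.10 to 7.14%) of genic reads could not be assigned to a single gene, against 6.63%, 6.42% and 6.73% in wild-type libraries 1, 2 and 3.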

How the results depend on the processing

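Among the alternatives, those on GC content within 40% to 55%, the later quasi-likelihood method, the GC-matched random lists and the trend removal for ARID1B and the wild-type comparisons were chosen after seeing the data. The 763 genes became 1775 with DESeq2 (724 of the 763 among them), 3226 of 30709 with no filter on low counts, 213 against a 1.5-fold null and 323 of 9483 genes of 40% to 55% GC content, where fewer genes were tested. Leaving out a wild-type library gave 157 to 1189. The 747 genes changed at least 2-fold became 1519 with DESeq2, 2331 with no filter, 473 with the GC and length trend removed, 281 at 40% to 55% GC content, and 157 to 1167 with a library left out. The counts lay within 1.5 times of the first under RLE (861) and upper-quartile scaling (747), limma-voom (892), no robust shrinkage (767), a mean count of at least 50 (580) and the later quasi-likelihood method (838); the earlier method is the default of this edgeR version, so that this alternative moved nothing. Upper-quartile scaling put the median of all genes at -0.17, against -0.05 with TMM. The causes of the DESeq2 and unfiltered counts were not tested.

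The ARID1B log2 fold change turned to -0.20 with the trend removed and lay between 0.47 and 1.12 with a wild-type library left out, the latter without library 1 and past the threshold; in no alternative was ARID1B lower at an adjusted p below 0.05. Its adjusted p ranged from 0.026 to 0.873 over the alternatives. The 14 shifted lists became 0 with an estimated correlation and 1 with fry, the histone list (adjusted p = 0.0179), where 11 lists had an unadjusted p below 0.05; the other alternatives gave 10 to 17. The fry test compares a list with no change, not with the other genes as camera does, so its count answers another question. The quasi-likelihood settings do not enter camera and were not run for the lists. The interferon list also lost its call with upper-quartile scaling (0.0577), no filter (0.0722) and at 40% to 55% GC content (0.209). The BMP list reversed at 40% to 55% GC content (camera adjusted p = 0.916). With the trend removed the signs of ARID1A (-0.38), SMARCA4 (-0.41), SMARCB1 (-0.69), BICRA (-0.49), ARID2 (0.10) and JUND (-0.54) reversed, of which only JUND had passed, and ARID2 also reversed at 40% to 55% GC content (0.041); the cause was not tested beyond the trend itself. Limma-voom ended the calls of CDKN2B (0.107), NCALD (0.0506), TNFRSF19 (0.066), METTL7A (0.0561) and BMP4 (0.0523), and 40% to 55% GC content that of COL5A2 (0.0612), besides those given with the genes. Upper-quartile scaling ended those of RRP12 (0.0552), HERPUD1 (0.0501), ZIC2 (0.0522) and RBM24 (0.0536), no robust shrinkage those of EREG (0.0513) and RRP12 (0.0527), and a mean count of at least 50 those of SPRY2 (0.0535), RRP12 (0.0537) and HERPUD1 (0.0518). Of the 73 named genes that passed, 72 kept their sign in every alternative that gave them a value. The 394 genes of wild-type library 1 became 202 with RLE and 0 with the trend removed, and the 0 genes of wild-type library 2 became 325 with no filter. No paired analysis was possible because the shRNA arm had 1 library. Depth limits genes with low counts most, since 3 counts correspond to 0.342 CPM in the library labelled ARID1B shRNA and to 0.195 CPM in the deepest wild-type library.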

Other observations

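The tests of ARID1B, of the 9p21 genes and of the mitochondrial copies were chosen only after the result was seen. For the stress response genes, the trend removal was an alternative planned in advance whose bounds were set after its result was seen. Nuclear pseudogene copies of mitochondrial genes, chosen after their values were seen, took 4.55% ± 0.499 (SD, n = 3) of gene counts in wild type and 1.46% (exact 95% interval 1.45 to 1.47%) in the library labelled ARID1B shRNA. MTCO1P12, a copy of the gene for a cytochrome oxidase subunit, fell from 13130 ± 888 to 3567 CPM (log2 fold change -1.88, edgeR adjusted p = 0.0181). Of 19 tested copies 14 fell and none rose, and 18 had an unadjusted p below 0.05. The copies are nearly identical in sequence to the mitochondrial genes, whose 13 mRNAs had 0 counts in every library, so the origin of these reads is uncertain.

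ARID1B was not lower in the library labelled ARID1B shRNA. With the GC and length trend removed, the lowest correlation between wild-type libraries was 0.967, across genes. The highest to the library labelled ARID1B shRNA was 0.956, lower by 0.0107. That library thus stood apart, but a separate batch or culture state could set it apart whichever cells it holds. The correlations therefore cannot decide whether its label was swapped with that of a wild-type library. Whether the GC and length trend hides a lower level cannot be told apart from no lowering: the log2 fold change with the trend removed was -0.201, and 2 SE on either side reach from -1.41 to 1.01. A single wrong label, or an shRNA that left the mRNA level as it was, was not tested.

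The integrated stress response list had the highest median of the lists tested. The GC and length trend does not account for it, since with the trend removed the median log2 fold change was 2.38 (camera adjusted p = 1.49e-18; adjusted p = 0.683 with an estimated correlation). With the wild-type libraries thinned to the depth of the library labelled ARID1B shRNA the median was 2.32. Thinning lowers all genes of a library alike, so it could hardly move this median and does not decide on depth. State or handling of the single shRNA culture, such as spent medium, may raise these genes as well as the shRNA could, and with 1 library in that arm these cannot be told apart.

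CDKN2B had 3 neighbours on the short arm of chromosome 9, in band 9p21, that also had 0 counts in the library labelled ARID1B shRNA. They were MTAP (4.64 ± 2.81 CPM in wild type), KLHL9 (1.49 ± 1.06 CPM) and IFNA4 (1.86 ± 1.41 CPM), the last with near-identical paralogues. IFNK and SPATA31C1, also on chromosome 9 but outside this run, were at 0 there as well (18, 40 and 30, and 18, 53 and 20 wild-type counts). A deletion of the block alone leaves these zeros open. Lower depth and the GC trend do not account for the zeros of the block, since 98.4 counts were to be awaited over its 4 genes at the lowest wild-type level. A deletion of the block in the cells of the library labelled ARID1B shRNA is a candidate explanation. The 4 nearest expressed genes on each side had counts. Expressed here means at least 40 reads over the wild-type libraries together, which left 12772 genes, 18 of them at 0. Genes below that level were skipped in counting neighbours. A run of 4 neighbouring zeros arose at a permutation p of 1e-04, the smallest that 10000 permutations can give. The permutations placed zeros alike on all these genes, whatever their level. That p can therefore be too small if low-count genes lie together. No difference in the ratio of the 4 genes to one another was detected between the wild-type libraries (chi-square p = 0.819) while their sum was 13.7, 34.7 and 13.1 CPM, which is consistent with 1 cell population, of differing share, carrying all of these reads in the wild-type libraries. Both remain hypotheses found and tested on the same data, and no DNA measurement was used here. The counts do not say whether the zeros or the wild-type reads are the usual state of Daoy cells. Whether a mixture of cells in the wild-type libraries accounts for other lower genes was not tested.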
